A study of Homo sapiens with 12 samples.

How the data were processed

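RNA from human blood cells enriched for lacking HLA-DR and carrying CD33 was sequenced in 12 libraries, 4 ENL, 5 RR and 3 HC. Per the labels' protocols, RNA was isolated with Trizol and cleaned on a column, integrity numbers were above 7.0, libraries were made with a TruSeq kit, and 6 or 7 libraries shared a lane of an Illumina sequencer run with single-end reads of 50 bases. The lane, batch and day of a library are not given in the sources used here. The submitters' processing notes name TopHat2 2.0.6, Bowtie2 2.0.2, HTSeq, DESeq 1.5 and the human build hg19, without saying which step made which file. The annotation and the strand setting are not given in the sources used here. Because the reference available was of another build, no coordinates are reported.

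A table of raw read counts per gene symbol, deposited by the authors, was the input of the main tests. It held 33391 genes, and 60 Y-linked or X-inactivation genes were removed before any step. In 26 entries (0.198% of counts) the symbol had been turned into a date, and 2 of these were duplicated; they stayed in the totals and tests without being named. A further table of signal values, also deposited by the authors, gave counts per gene divided by 1 size factor per library for 21610 genes, of which 23 were removed for the same reason. All of its values (100%) were whole reads within 0.01 when multiplied by the size factor. The recovered totals lay close to those of the raw table in most libraries and at 1.42 times in ENL replicate 1, so the tables were not made from the same reads or settings there; 15822 symbols were in both.

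Groups and replicate numbers came from the sample titles and the diagnosis from the labels. Libraries of a group differed by far more than sampling noise (lowest chi-square per degree of freedom 80.5), so none was counted as a duplicate. The main test was edgeR 4.0.16 in R 4.3.3. Counts were scaled with TMM (factors 0.684 to 1.45), and genes were kept by filterByExpr (18775 tested, 14556 removed). All 12 libraries were fitted in 1 quasi-likelihood model with robust dispersion and a term per group, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.783. Leprosy against HC used the mean of the ENL and RR terms. CPM values used the TMM-scaled totals, and log2 CPM a prior count of 2. The groups, tests, gene lists, the rule for named genes and the alternatives listed first were chosen before the data were examined.

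The 30 gene lists covered stress responses, suppressor cell genes, interferon and inflammatory responses, metabolism, proliferation and markers of cell types that the enrichment could hold. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 30 lists of a comparison and at least 5 tested members each. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move on balance one way, or change in either direction, and compares a list with no other genes. No list call held with an estimated correlation. List medians used fitted fold changes; with members at 0 in a whole group set to a floor of 3 reads over the group, 0 medians changed.

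Named genes were, per pairwise comparison, the 12 highest and 12 lowest that passed or, where none did, the 5 higher and 5 lower genes with the smallest unadjusted p and a mean of at least 5 CPM; a fixed set of ER stress, suppressor and sorting genes; and up to 4 members of each called list with the smallest p in its direction. The text gives a selection of these. For leprosy against HC the first part of the rule was extended after the data had been seen. Genes whose reads can be shared with copies (GOLGA8A, CCL3 and CCL4, HSPA1A and HSPA1B, hemoglobin genes, the mitochondrial pseudogenes MTND4P12 and MTCO1P12) and antisense genes such as VIM-AS1 are uncertain.

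The alternatives chosen beforehand were RLE factors (the DESeq2 type), library totals, no filter, a stricter filter of 1 CPM, non-robust fitting, the replicate number as a block, counts without hemoglobin and mitochondrial genes, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the authors' normalized values plus 1 (genes with a value of at least 10 in at least 3 libraries), only the groups compared, a 2-fold minimum, an adjusted p under 0.10, and each library left out. After the data were seen 5 more were added: reads recovered from the normalized table, 1 surrogate variable from sva 3.50.0, voom with library weights, and the T cell or classical monocyte score as a covariate. Total counts ran from 7300353 to 79745192, and counting error is relatively larger in the smaller libraries; the test rests on the spread between libraries, which was above counting error. In data simulated from the real means and totals, with 50 genes per fold, edgeR recovered 34, 18, 36 and 36% of genes changed 4-fold and 82, 80, 86 and 84% of those changed 16-fold for ENL against RR, ENL against HC, RR against HC and leprosy against HC (17713, 17792, 17762 and 17794 genes). In the same order it called 2, 1, 1 and 10 unchanged genes, and DESeq2 55, 51, 86 and 73. The simulated genes varied independently, without differences shared by many genes of a library.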

Results

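Gene expression was measured by RNA sequencing in myeloid-derived suppressor cells (MDSC), immature myeloid cells that restrain lymphocytes, taken from human blood. Cells lacking HLA-DR and carrying CD33 had been enriched with magnetic beads from blood mononuclear cells and received no treatment. The 12 libraries fell into 4 labelled ENL, 5 labelled RR and 3 labelled HC. Both ENL and RR carried the diagnosis leprosy and HC the diagnosis healthy. The labels do not spell the names out. In common leprosy usage they stand for erythema nodosum leprosum and reversal reaction, inflammatory episodes of that disease. The series title names endoplasmic reticulum (ER) stress, MDSC function and interferon gamma as its subjects, and the 4 comparisons ask how the groups differed in these and in the other gene groups fixed beforehand. Total counts covered 12237327 to 79745192 in ENL, 10658324 to 51231872 in RR and 7300353 to 42004196 in HC, a 10.9-fold range. The smallest total was that of HC replicate 1, where low-expressed genes were counted least precisely. The labels say no more of the replicates than that they are separate samples from several patients and donors, and the p-values measure the spread between these samples. Expression is given as CPM, counts scaled to the size of the library, as mean ± SD, and fold changes as log2 with the standard error (SE) of the fit.

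**Figure D1:**
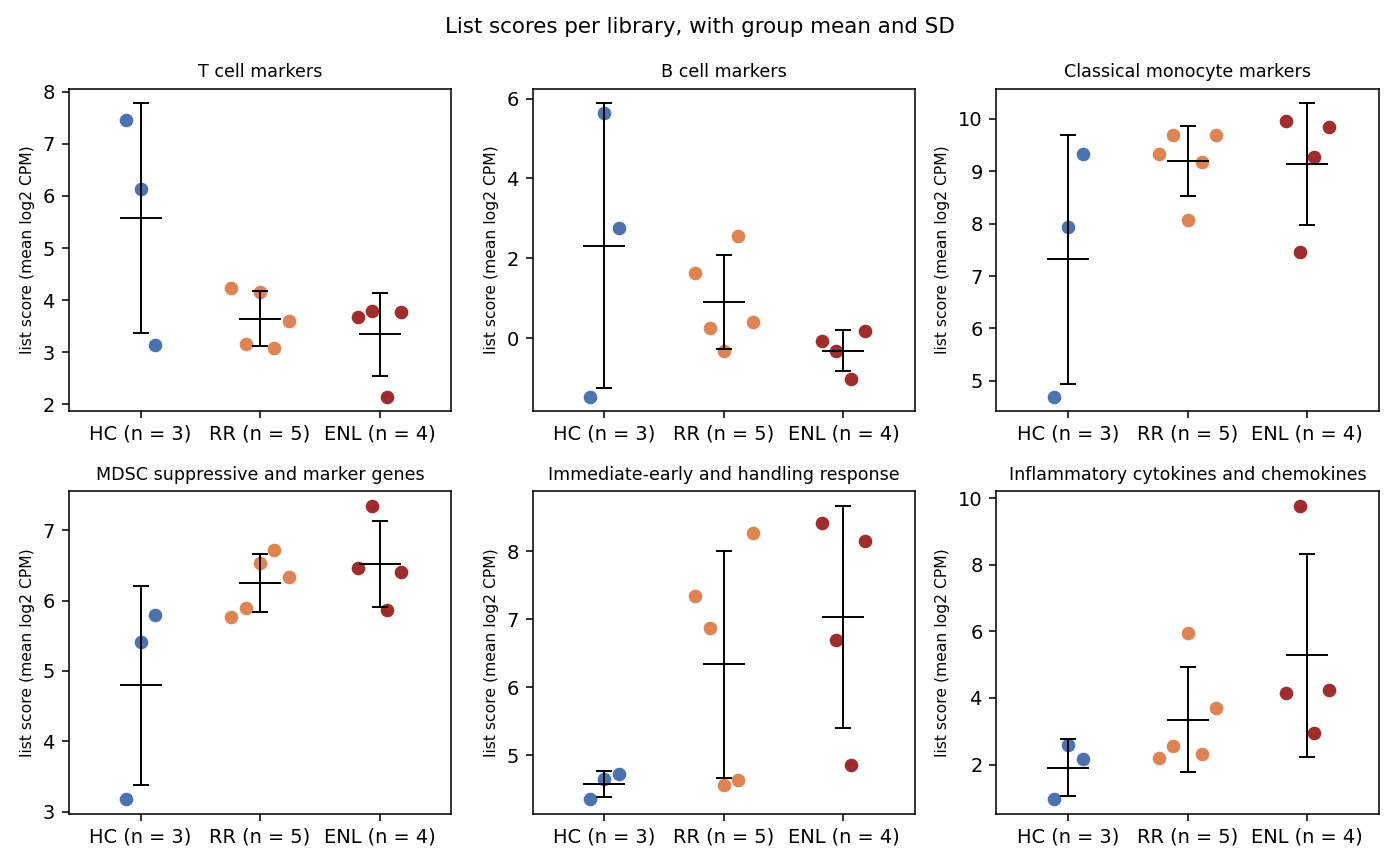
List scores of 6 gene lists per library, the mean log2 CPM of a list's members on the vertical axis, with 1 point per library and the group mean and SD as a line and bar for HC (n = 3), RR (n = 5) and ENL (n = 4). T cell scores were 7.45, 6.12 and 3.15 in the 3 HC libraries and 2.15 to 4.22 in the 9 leprosy libraries, and 1 ENL library had a cytokine score of 9.77.

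Cell division genes and B cell markers were lower as lists in ENL than in RR. The 2 lists were called by camera with Benjamini-Hochberg adjusted p of 1.42e-10 and 4.7e-05, and neither with an estimated correlation (adjusted p = 0.735 with an estimated correlation for each). The cell cycle list had a median log2 fold change of -1.62, with 1 of 24 members positive. MKI67, a marker of proliferating cells, was at 5.48 ± 1.88 CPM in ENL (n = 4) and 33.4 ± 43.2 in RR (n = 5), and the mitotic motor KIF11 at 2.18 ± 0.385 and 6.83 ± 4.87, log2 fold changes of -2.60 (SE 1.06) and -1.65 (SE 0.59). B cell markers had a median of -1.82, with 2 of 14 members positive. MS4A1, which encodes CD20, was at 1.57 ± 1.06 CPM in ENL and 12.5 ± 18.6 in RR. No member passed by edgeR over all genes or adjusted over the list alone (0 of each). The cell cycle score was 2.77 in RR replicate 1 and 3.28 in RR replicate 4, against -0.09, 0.45 and 0.59 in RR replicates 2, 3 and 5 and -0.54 to 0.72 in ENL. MKI67 was at 53.2 and 101 CPM in those RR libraries and at 1.73 to 7.10 in the other 3. Markers of other cells were also high in them: the plasma cell score was 5.45 in RR replicate 1 (0.23 to 2.58 in the other RR libraries), and the immature neutrophil granule score was 6.50 in RR replicate 4 (-0.11 to 2.98 in the others). The B cell score was 1.64 and 2.57 in RR replicates 1 and 4 and -0.32 to 0.41 in the other 3. Both calls held without any 1 of the 12 libraries, with the B cell median at -0.97 without RR replicate 4 and cell cycle medians between -1.88 and -1.09. Each of those fits kept RR replicate 1, RR replicate 4 or both, so it cannot tell whether the calls rest on this pair. A fit without the pair was not run, and the other RR libraries had cell cycle scores in or near the ENL range.

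Inflammatory cytokine genes and genes of hypoxia and glycolysis were higher as lists in ENL than in RR by camera, and both calls were lost when a single library was left out. Adjusted p by camera was 2.48e-08 and 2.87e-06, and adjusted p = 0.735 with an estimated correlation for each. The cytokine list had a median of 3.19 with 21 of 23 members positive, and the hypoxia list 0.98 with 21 of 22 positive. IL1B, a fever-inducing cytokine, averaged 9854 ± 18551 CPM in ENL (n = 4) against 315 ± 369 in RR (n = 5), and IL6 was at 2746 CPM in ENL replicate 2 and between 0.0667 and 2.26 in the other 3 ENL libraries. Without ENL replicate 2 the medians were -0.25 and -0.06 and neither list was called. Of the cytokine genes 0 passed by edgeR over all genes and 13 were higher adjusted over the list alone, against 0 and 0 for the hypoxia list.

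The ER chaperone and degradation genes, the arm of the ER stress response run by ATF6 and XBP1, were higher in ENL than in RR by a small amount, with a median of 0.23 and 26 of 28 members positive (camera adjusted p = 0.00653, and adjusted p = 0.735 with an estimated correlation). HSPA5, the main ER chaperone, was at 463 ± 164 CPM in ENL (n = 4) and 343 ± 61.0 in RR (n = 5), log2 0.43 (SE 0.32), and XBP1, a transcription factor of that arm, at 168 ± 46.0 and 112 ± 34.7, log2 0.59 (SE 0.28). Interferon gamma response genes were lower in ENL, with a median of -0.44 and 3 of 26 members positive (camera adjusted p = 0.00257, and adjusted p = 0.735 with an estimated correlation). APOL3 was at 58.7 ± 33.2 CPM against 108 ± 63.6, and PSMB9, a subunit of the immunoproteasome, at 46.7 ± 21.5 against 74.1 ± 19.7. By edgeR 0 members of either list passed over all genes or adjusted over the list alone. The chaperone call was lost without ENL replicate 2, ENL replicate 3, RR replicate 2 or RR replicate 5 (medians 0.13, 0.03, 0.16 and 0.15), and the median was 0.36 without ENL replicate 1. The interferon gamma call was lost without ENL replicate 3 (-0.17), and the median was -0.24 without RR replicate 1. The PERK, ATF4 and CHOP arm of the stress response had a median of 0.29 and was not called (camera adjusted p = 0.208).

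No single gene passed the test between ENL and RR. Of 18775 genes, edgeR quasi-likelihood with Benjamini-Hochberg adjustment called 0, with a smallest adjusted p of 0.9998. At an unadjusted p under 0.05 there were 467 genes, 285 higher and 182 lower, where chance gives 939; DESeq2 and limma-voom also called 0, with 648 and 419 at unadjusted p under 0.05. The groups did not overlap in 123 genes (0.66%), against 1.59% by chance. IL10, which encodes a suppressive cytokine, was at 7.27 ± 9.85 CPM in ENL (n = 4) and 0.688 ± 0.474 in RR (n = 5), log2 3.39 (SE 0.93), edgeR unadjusted p = 0.00322. It was at 22 CPM in ENL replicate 2 and 1.38 to 3.38 in the other 3 ENL libraries, and the log2 fold change was 1.78 without ENL replicate 2. Among the genes with the smallest p, all of which failed the correction, PRDM8 was at 13.6 ± 6.55 CPM in ENL and 4.07 ± 1.58 in RR, and NHLRC3 and the mitochondrial magnesium channel gene MRS2 were at 28.6 ± 11.8 against 53.7 ± 9.54 and 11.9 ± 1.84 against 19.7 ± 3.21. IFNG, the gene of interferon gamma itself, was at 4.74 ± 8.60 CPM in ENL and 2.52 ± 2.58 in RR, with 17.6 CPM in ENL replicate 4 and 0 to 1.24 in the other 3 ENL libraries; without ENL replicate 4 its log2 fold change of 0.92 turned negative. Of the 30 lists camera called 13, 5 higher and 8 lower; with an estimated correlation and by both tests of fry the number was 0 each, and 0 had an unadjusted p under 0.05 with an estimated correlation or in fry's test of a move in 1 direction.

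Against HC, ENL libraries had higher expression of the MDSC list and of immediate-early and hypoxia genes and lower expression of T cell markers. By camera the adjusted p was 4.93e-07, 5.06e-08, 1.25e-08 and 1.12e-11 for the MDSC, immediate-early, hypoxia and T cell lists, and adjusted p = 0.402 for the first and 0.409 for the others with an estimated correlation. The MDSC list had a median of 1.52 with 20 of 23 members positive. The inflammatory calcium-binding protein gene S100A9 was at 3955 ± 2998 CPM in ENL (n = 4) and 328 ± 247 in HC (n = 3), log2 3.59 (SE 0.89). PTGS2, the inducible enzyme of prostaglandin synthesis, was at 1946 ± 2334 against 11.4 ± 5.82. Immediate-early genes, which are switched on within minutes of a stimulus or of handling, had a median of 3.08 with 23 of 25 positive, and hypoxia and glycolysis genes 2.0 with 22 of 22 positive. The glycolytic enzyme gene GAPDH, which can share reads with its pseudogenes, was at 1961 ± 1214 CPM against 375 ± 103. T cell markers had a median of -2.68 with 0 of 20 positive, and CD3G, a chain of the T cell receptor complex, was at 6.31 ± 0.844 CPM against 65.5 ± 72.7. The T cell difference rested on HC replicates 1 and 2. In HC replicate 3 CD3G was at 3.86 CPM, below every ENL library (5.36 to 7.15). The T cell score there was 3.15, inside the ENL range of 2.15 to 3.79. By edgeR 0 members of these lists passed over all genes, while adjusted over the list alone 7, 16 and 13 were higher in the first 3 and 17 lower among the T cell markers. These calls held without any 1 library, with a hypoxia median of 1.05 without ENL replicate 2 and a T cell median of -1.75 without HC replicate 1.

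The ER stress lists lay higher in ENL than in HC. Camera adjusted p was 0.00703 for the PERK, ATF4 and CHOP list and 0.021 for the chaperone list, and adjusted p = 0.409 and 0.624 with an estimated correlation. The PERK, ATF4 and CHOP list, which covers the translation-control arm of the stress response, had a median of 1.02 with 17 of 25 members positive. ATF4, its central transcription factor, was at 218 ± 45.7 CPM in ENL (n = 4) and 103 ± 15 in HC (n = 3), log2 1.08 (SE 0.37). DDIT3, which encodes CHOP, was at 31.3 ± 12.3 and 12.4 ± 4.80. PPP1R15A, which restores translation after stress, was at 995 ± 615 and 60.8 ± 22.2. The chaperone list had a median of 0.36 with 24 of 28 positive, and HSPA5 was at 463 ± 164 CPM against 301 ± 135. For the PERK list 0 members passed by edgeR over all genes and 7 were higher and 1 lower adjusted over the list alone. For the chaperones both counts were 0. The PERK median was 0.58 without ENL replicate 2. The chaperone call was lost without ENL replicate 2 (0.36), ENL replicate 3 (0.17) or HC replicate 1 (0.07), with 0.58 without HC replicate 3. T cell scores were high in HC replicates 1 and 2 (7.45 and 6.12), while HC replicate 3 (3.15) lay inside the ENL range of 2.15 to 3.79.

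Classical monocyte, mature neutrophil and platelet markers were higher as lists in ENL than in HC and B cell markers lower, while their scores per library overlapped between the groups. Camera adjusted p was 1.17e-05, 0.00112, 0.00104 and 2.98e-05 in that order, and adjusted p = 0.409, 0.409, 0.429 and 0.409 with an estimated correlation. Scores were 7.45 to 9.96 in ENL and 4.70 to 9.34 in HC for monocyte, 2.62 to 5.05 and 1.76 to 3.07 for neutrophil, -2.08 to 3.44 and -1.38 to 0.09 for platelet, and -1.03 to 0.18 and -1.46 to 5.63 for B cell markers. Classical monocyte markers had a median of 1.05 with 17 of 18 positive. CD14, the monocyte receptor for bacterial lipopolysaccharide, was at 1793 ± 902 CPM in ENL (n = 4) and 234 ± 196 in HC (n = 3), log2 2.94 (SE 0.79). Mature neutrophil markers had a median of 1.88 with 16 of 20 positive, and platelet markers 2.76 with 14 of 14 positive. B cell markers had a median of -4.78 with 1 of 14 positive. Inflammatory cytokines had a median of 6.40 with 22 of 23 positive (camera adjusted p = 1.53e-06, and adjusted p = 0.409 with an estimated correlation), with a median of 2.01 without ENL replicate 2. CXCL8, a neutrophil chemoattractant, was at 15662 ± 24880 CPM against 82.4 ± 25.7. Adjusted over the list alone 2, 2, 0, 12 and 15 members passed by edgeR for the monocyte, neutrophil, platelet, B cell and cytokine lists, against 0 over all genes. The monocyte median was 0.48 without HC replicate 1 and 2.33 without HC replicate 3, and the B cell median was -2.49 without HC replicate 2.

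No single gene passed the test between ENL and HC by edgeR quasi-likelihood with Benjamini-Hochberg adjustment (0 of 18775, smallest adjusted p = 0.1263). The closest included MCEMP1, a myeloid surface protein gene, at 83.5 ± 82.6 CPM in ENL (n = 4) and 2.13 ± 1.14 in HC (n = 3), log2 5.29 (SE 0.82). SESN3, a stress-response gene of the sestrin family, was at 67.1 ± 11.7 against 275 ± 108, log2 -2.03 (SE 0.32). P2RY10, a lymphocyte receptor gene, was at 12.4 ± 3.32 CPM against 57.8 ± 7.49, the transcription factor gene TSHZ3 at 30.3 ± 5.19 against 7.84 ± 4.10, and CKAP4, an ER membrane protein gene, at 255 ± 142 against 20.9 ± 11.6. IL10 had 6 reads in all over the 3 HC libraries and a mean of 0.0378 CPM there, too few for a fold. At an unadjusted p under 0.05 there were 3321 genes, 1665 higher and 1656 lower, where chance gives 939, and 3053 genes (16.3%) did not overlap between the groups against 5.71% by chance. DESeq2 called 1467 genes, limma-voom 0, and edgeR without HC replicate 3 120. Camera called 19 of the 30 lists, 14 higher and 5 lower, against 0 with an estimated correlation (2 at unadjusted p under 0.05) and 0 in fry's test of a move in 1 direction (5 at unadjusted p under 0.05). Fry's test of change in either direction called 5 lists. These were the PERK, ATF4 and CHOP list, the MDSC list, scavenger and alternatively activated macrophage genes and vitamin D and antimicrobial genes (fry adjusted p = 0.0278 each), and complement and Fc receptor genes (0.0452).

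In RR, the MDSC, classical monocyte and immediate-early lists were higher than in HC and T cell markers lower. Camera adjusted p was 9.85e-08, 5.91e-07, 3.4e-06 and 1.73e-12 in that order, and adjusted p = 0.274 for the MDSC list and 0.384 for the other 3 with an estimated correlation. The MDSC list had a median of 1.63 with 20 of 23 members positive. S100A9 was at 3795 ± 1632 CPM in RR (n = 5) and 328 ± 247 in HC (n = 3), log2 3.53 (SE 0.87). S100A8, its partner in the calprotectin complex, was at 1472 ± 572 against 192 ± 184, and S100A12, of the same family, at 337 ± 128 against 29.2 ± 27.4. Classical monocyte markers had a median of 1.09 with 17 of 18 positive, and CD14 was at 1032 ± 533 CPM against 234 ± 196. Immediate-early genes had a median of 1.97 with 22 of 25 positive. T cell markers had a median of -2.45 with 0 of 20 positive, and LEF1, a transcription factor of T cell development, was at 5.77 ± 2.45 CPM against 65.0 ± 67.3. In HC replicate 3 LEF1 was at 5.03 CPM and the T cell score at 3.15, inside the RR ranges of 3.17 to 9.39 CPM and 3.08 to 4.22. By edgeR 0 members passed over all genes. Adjusted over the list alone 4, 0 and 0 were higher and 19 T cell markers lower. The calls held without any 1 library, but scores per library overlapped for the 3 higher lists as well. MDSC scores were 5.77 to 6.72 in RR and 3.18, 5.42 and 5.79 in HC replicates 1, 2 and 3. Monocyte scores were 8.06 to 9.70 in RR and 4.70, 7.93 and 9.34 in the same HC libraries. Immediate-early scores were 4.56 to 8.27 in RR and 4.35 to 4.72 in HC. The monocyte median was 0.50 without HC replicate 1 and 2.23 without HC replicate 3, and the T cell median -1.45 without HC replicate 1.

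Of the ER stress lists the PERK, ATF4 and CHOP list was higher in RR than in HC, with a median of 1.0 and 19 of 25 members positive. ATF4 was at 207 ± 77.5 CPM in RR (n = 5) and 103 ± 15 in HC (n = 3), and CEBPB, a transcription factor of myeloid stress responses, at 217 ± 131 against 34.2 ± 19.9, log2 2.67 (SE 0.71). ERN1, a member of the chaperone list that encodes the ER stress sensor IRE1, was at 111 ± 43.4 CPM against 226 ± 137. The HC mean rested on HC replicate 1 (379 CPM). HC replicates 2 and 3 (184 and 114) lay inside the RR range of 76.1 to 186. For the PERK list camera adjusted p was 0.0123, and adjusted p = 0.48 with an estimated correlation. In that list 0 members passed by edgeR over all genes and 0 adjusted over the list alone. The call was lost without RR replicate 3 (median 0.38). The chaperone list had a median of 0.20 and the interferon gamma response list 0.02, and neither was called (camera adjusted p = 0.303 and 0.244). Immature neutrophil granule genes had a median of 2.42 with 20 of 20 positive (camera adjusted p = 0.0123, and adjusted p = 0.642 with an estimated correlation), and MPO, a granule enzyme gene, was at 21.7 ± 17.0 CPM against 5.22 ± 3.80. That call was lost without HC replicate 1 (1.84) and without RR replicate 4, where the median was -1.20.

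No single gene passed the test between RR and HC by edgeR quasi-likelihood with Benjamini-Hochberg adjustment (0 of 18775, smallest adjusted p = 0.2465). The smallest p-values belonged to NELL2, a secreted protein gene, at 3.21 ± 0.985 CPM in RR (n = 5) and 54 ± 45.2 in HC (n = 3), log2 -4.06, and to P2RY10. The latter was at 12.3 ± 4.88 CPM against 57.8 ± 7.49, log2 -2.23 (SE 0.35). TRAF5, a signalling adaptor of lymphocytes, was at 13.5 ± 4.34 CPM against 77.1 ± 34.5, and MCEMP1 at 41.9 ± 17.0 against 2.13 ± 1.14. At an unadjusted p under 0.05 there were 2190 genes, 1025 higher and 1165 lower, where chance gives 939. Overlap between the groups was absent in 1529 genes (8.14%) against 3.57% by chance. DESeq2 called 450 genes and limma-voom 0; edgeR called 54 without HC replicate 3 and 1 without RR replicate 4. Camera called 19 of the 30 lists, 16 higher and 3 lower, against 0 with an estimated correlation (2 at unadjusted p under 0.05) and 0 in fry's test of a move in 1 direction (4 at unadjusted p under 0.05). The MDSC list was called by fry's test of change in either direction (fry adjusted p = 0.0492). Because ENL and RR were set against the same HC libraries, their differences from HC are not independent, and a difference between the leprosy groups was tested only by ENL against RR.

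**Figure D2:**
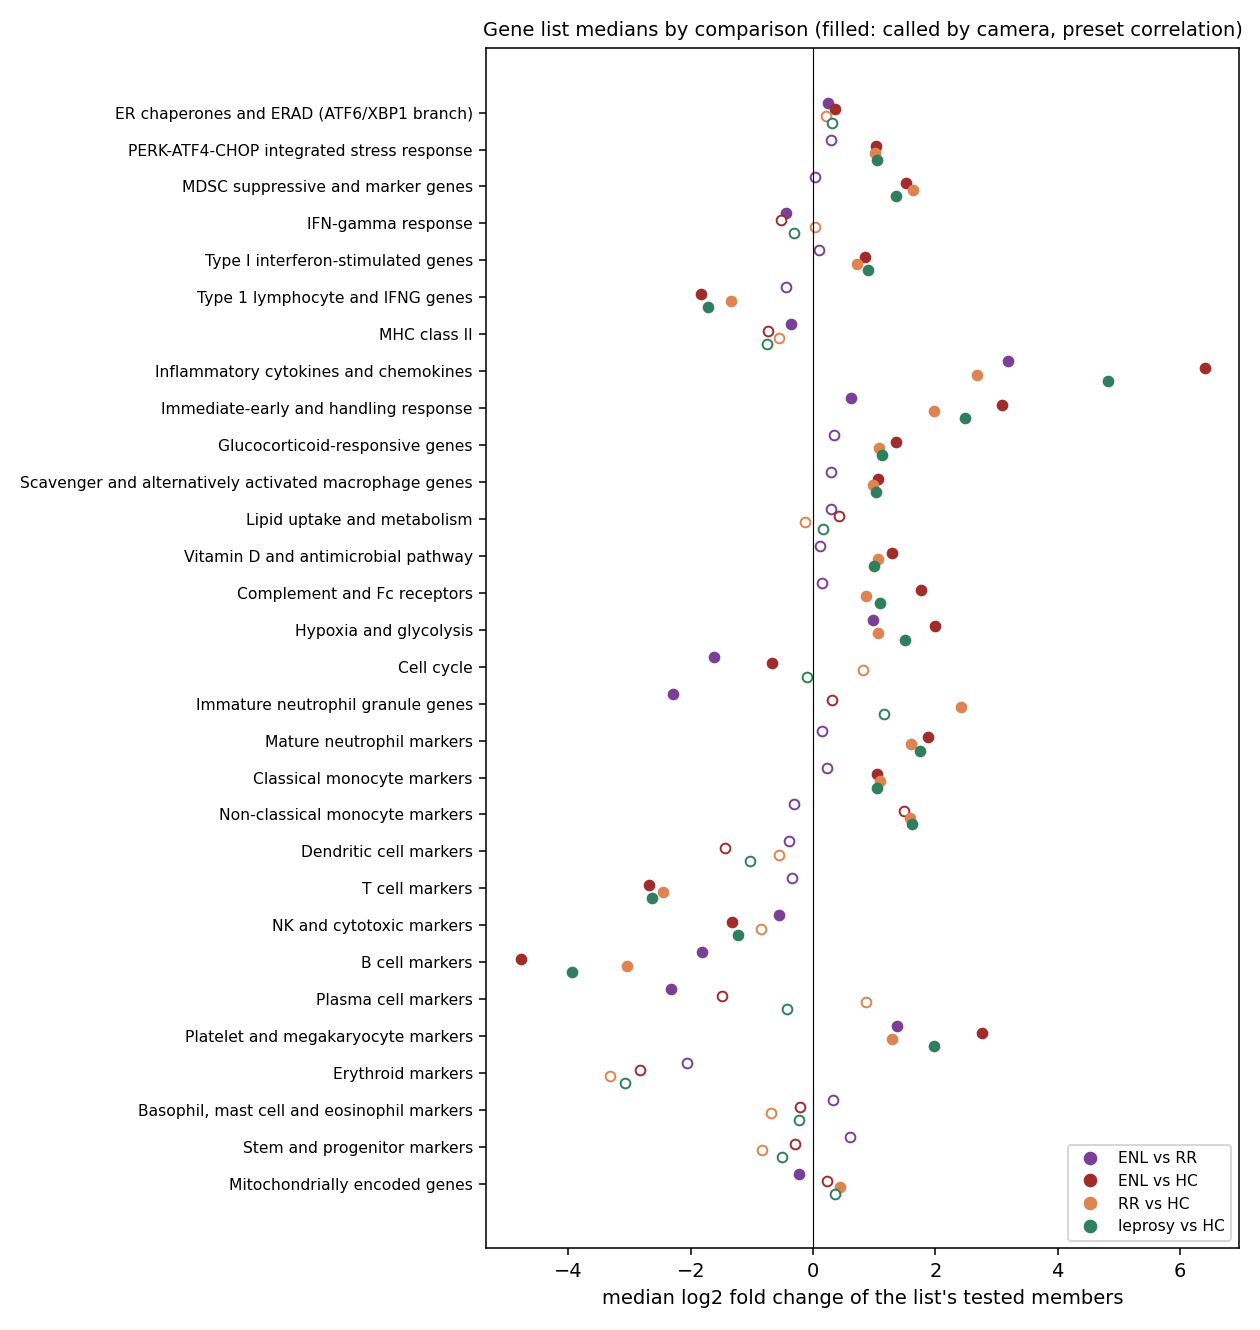
Median log2 fold change of each of the 30 gene lists (horizontal axis) in the 4 comparisons, 1 point per list and comparison, filled where camera with its preset correlation called the list. T cell markers lay at -2.68, -2.45 and -2.63 against HC in ENL, RR and all leprosy libraries and at -0.34 between ENL and RR, where they were not called.

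With the 9 leprosy libraries set against the 3 HC libraries, 44 genes differed, 1 higher and 43 lower, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. MCEMP1 rose from 2.13 ± 1.14 CPM in HC (n = 3) to 60.4 ± 56.4 in leprosy (n = 9), log2 4.79 (SE 0.77, edgeR adjusted p = 0.03821). Of the genes that fell, NELL2 went from 54 ± 45.2 to 3.48 ± 0.978 CPM, log2 -3.94 (SE 0.50, edgeR adjusted p = 0.03821), and TRAT1, an adaptor of the T cell receptor, from 36.7 ± 32.6 to 5.90 ± 1.35, log2 -2.63 (SE 0.44, edgeR adjusted p = 0.04432). S1PR1, the receptor by which lymphocytes leave lymphoid organs, fell from 177 ± 150 to 30.6 ± 11 CPM, log2 -2.52. BACH2, a transcription factor of B and T lymphocytes, fell from 42.5 ± 20.6 to 5.06 ± 3.17 CPM and DPP4, the surface peptidase CD26, from 22.1 ± 14.7 to 2.40 ± 1.48, log2 -3.12 and -3.23. TRAF5 fell from 77.1 ± 34.5 to 12.5 ± 5.23 CPM and LIMA1, an actin-binding protein gene, from 21.0 ± 3.42 to 4.56 ± 1.93. The T cell score was 7.45, 6.12 and 3.15 in HC replicates 1, 2 and 3 and 2.15 to 4.22 in leprosy. It was thus high in HC replicates 1 and 2 like these genes, while HC replicate 3 lay in the leprosy range. In HC replicate 3 LIMA1 was at 24.4 CPM, above every leprosy library (2.25 to 8.27). The called gene LY9 was not above them there (log2 CPM 2.54, leprosy 1.90 to 3.55). The genes without group overlap numbered 941 (5.01%), against 0.91% by chance. DESeq2 called 1568 genes and limma-voom 104, while with the T cell score or the monocyte score as a covariate edgeR called 0. With the replicate number as a block it called 0, and limma on the authors' normalized values called 1 gene, which was not among the 44. Leaving out any of the 12 libraries moved the count by over 1.5 times. It was 318 without HC replicate 3, 25 without RR replicate 4, 17 without RR replicate 1, 9 without ENL replicate 3, 2 without RR replicate 3, and 0 without ENL replicates 1, 2 or 4, RR replicates 2 or 5, or HC replicates 1 or 2.

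T cell and B cell markers were lower as lists in leprosy than in HC by camera, and MDSC, monocyte, immediate-early, hypoxia and PERK, ATF4 and CHOP genes higher. None of these 7 lists was called with an estimated correlation (adjusted p = 0.316 for the MDSC list and 0.415 for the other 6 with an estimated correlation). T cell markers had a median of -2.63 with 0 of 20 positive. TRAT1 passed by edgeR over all genes and all 20 adjusted over the list alone. The B cell markers had a median of -3.95 with 1 of 14 positive; MS4A1 was at 7.67 ± 14.4 CPM in leprosy (n = 9) and 237 ± 362 in HC (n = 3). By edgeR 0 members passed over all genes and 12 adjusted over the list alone. The MDSC list had a median of 1.35 with 21 of 23 positive, classical monocyte markers 1.04 with 17 of 18, immediate-early genes 2.48 with 23 of 25, hypoxia genes 1.5 with 21 of 22 and the PERK, ATF4 and CHOP list 1.04 with 19 of 25. S100A9 was at 3866 ± 2170 CPM in leprosy against 328 ± 247, log2 3.56 (SE 0.85), and the phosphatase gene DUSP1, an immediate-early gene, had a log2 fold change of 6.02 (SE 1.78). FOS, of the same list, was at 5141 to 15075 CPM in ENL replicates 1 and 4 and RR replicates 1, 2 and 5, at 64.5 to 164 in the other 4 leprosy libraries and at 22.4 to 92.7 in HC. ATF4 was at 212 ± 61.8 CPM against 103 ± 15 and DDIT3 at 28.2 ± 9.81 against 12.4 ± 4.80, with edgeR adjusted p of 0.147 and 0.16. Adjusted over the list alone 6, 2, 0 and 6 members of the MDSC, monocyte, immediate-early and hypoxia lists were higher, and 6 higher and 1 lower in the PERK list, against 0 over all genes.

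By camera the adjusted p in leprosy against HC was 9.57e-15 for T cell, 2.06e-05 for B cell, 3.29e-07 for MDSC, 2.29e-06 for monocyte, 4.18e-07 for immediate-early, 3.83e-07 for hypoxia and 0.0108 for PERK, ATF4 and CHOP genes. The B cell call was lost without HC replicate 2 (median -1.35). The other 6 calls held without any 1 library. The T cell median was -1.67 and the monocyte median 0.46 without HC replicate 1, the MDSC and monocyte medians 2.11 and 2.31 without HC replicate 3, and the PERK median 0.67 without ENL replicate 2 and 0.66 without RR replicate 3. The chaperone list (median 0.30, 22 of 28 positive) and the interferon gamma response list (-0.32) were not called, with camera adjusted p of 0.0696 and 0.789. Camera called 18 of the 30 lists, 14 higher and 4 lower, against 0 with an estimated correlation (3 at unadjusted p under 0.05) and 0 in fry's test of a move in 1 direction (7 at unadjusted p under 0.05). In its test of change in either direction fry called 4, the MDSC list and the scavenger and alternatively activated macrophage list (fry adjusted p = 0.0157 each) and the PERK, ATF4 and CHOP and vitamin D lists (0.0332 each).

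Type 1 lymphocyte and IFNG genes were lower as a list than in HC, with medians of -1.84 in ENL, -1.34 in RR and -1.72 in leprosy and 1 of 12 members positive in each. The positive member was IFNG itself, which in ENL rested on ENL replicate 4 (17.6 CPM, with 0 to 1.24 in the other 3 ENL libraries and 0 to 1.0 in HC); without it the log2 fold change against HC went from 2.97 to -0.30 in ENL and from 2.51 to 0.88 in leprosy. IL18R1, a chain of the interleukin 18 receptor, was at 14.4 ± 7.72 CPM in leprosy (n = 9) and 47.8 ± 20.2 in HC (n = 3), log2 -1.73 (SE 0.47), and CXCR3, a chemokine receptor of type 1 T cells, at 4.04 ± 4.54 and 31 ± 39.7. By camera the adjusted p in ENL, RR and leprosy was 0.00224, 0.00841 and 0.00207, and adjusted p = 0.429, 0.557 and 0.432 with an estimated correlation. By edgeR 0 members passed over all genes, and adjusted over the list alone IL18R1 was lower in leprosy and 0 passed in ENL or RR. Without HC replicate 1, whose T cell score was 7.45, none of the 3 calls was kept (medians -0.88, -0.46 and -0.66). The RR call was also lost without RR replicate 4 (-1.10), with -2.03 without RR replicate 1, and the ENL median was -2.93 without ENL replicate 4.

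**Figure D3:**
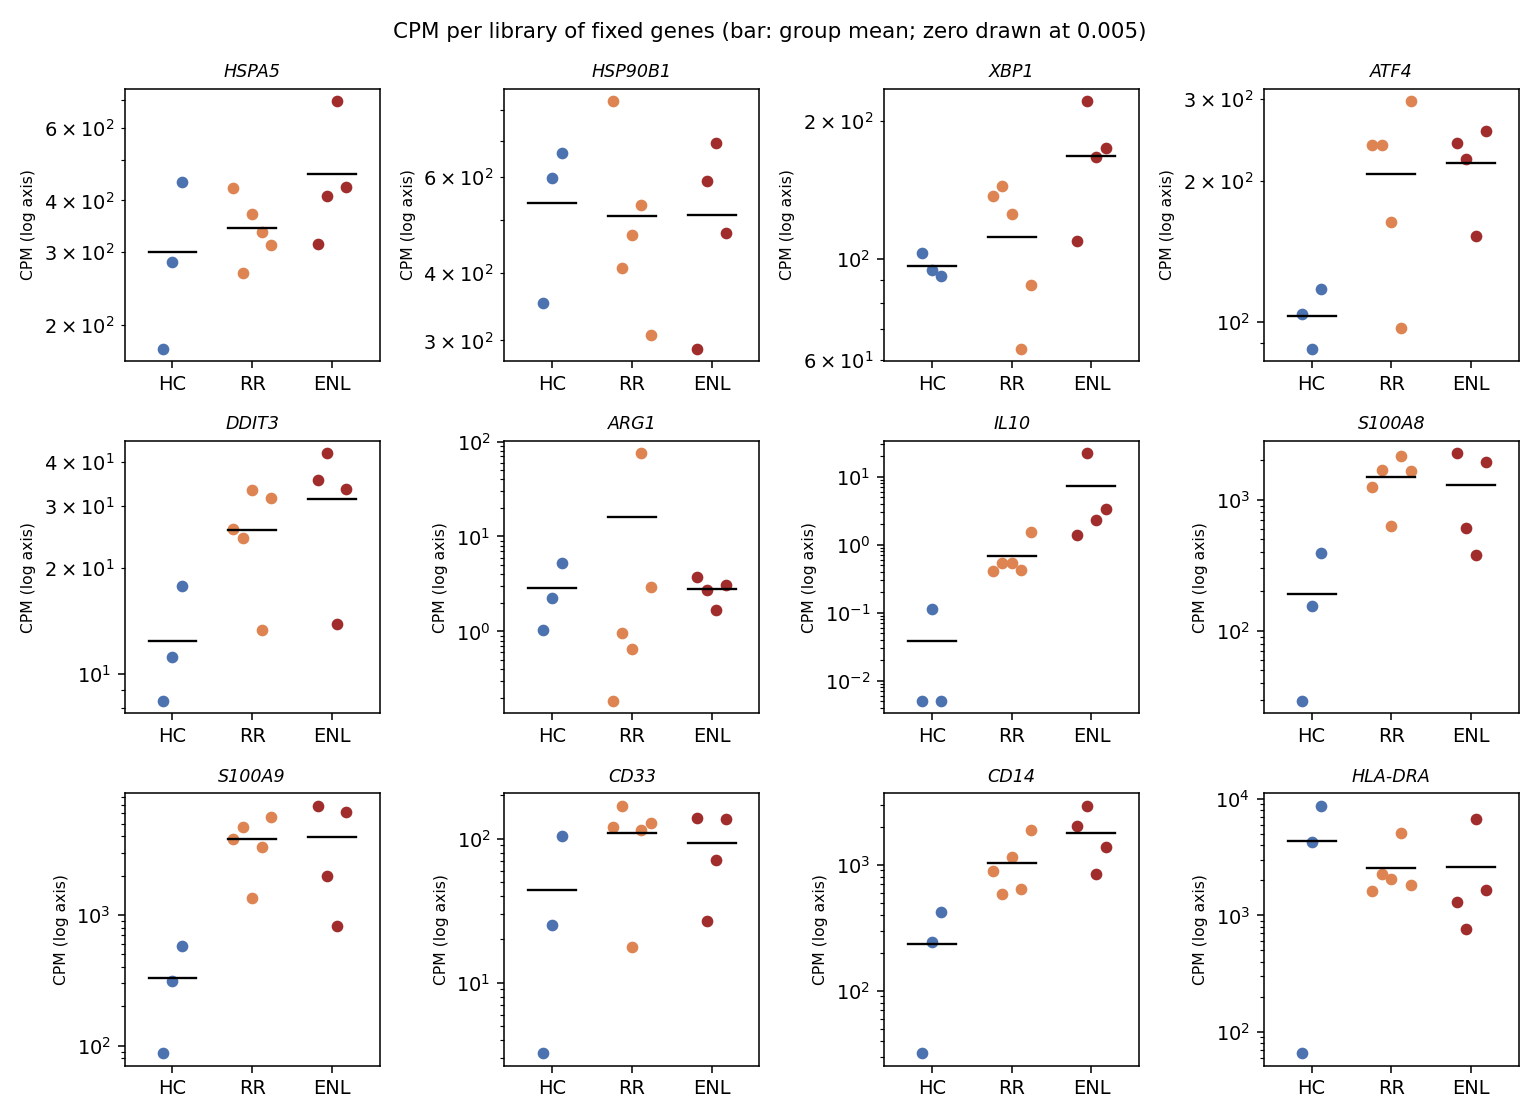
CPM per library (vertical log axis, values of 0 drawn at 0.005) of 12 of the genes fixed beforehand in HC (n = 3), RR (n = 5) and ENL (n = 4), 1 point per library with a bar at the group mean. ATF4 had means of 103, 207 and 218 CPM, and HSP90B1 means of 538, 509 and 512, in HC, RR and ENL.

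The remaining fixed genes did not pass the edgeR test between leprosy and HC. The ER chaperone gene HSP90B1 was at 510 ± 175 CPM in leprosy (n = 9) and 538 ± 165 in HC (n = 3), the PERK gene EIF2AK3 at 41.0 ± 12.4 and 39.7 ± 8.45, and ATF6 at 116 ± 37.2 and 92.1 ± 38.4. The arginine-degrading enzyme gene ARG1 was at 10.1 ± 24.4 CPM against 2.84 ± 2.14, the granulocyte marker CEACAM8 at 30.7 ± 79.9 against 11.5 ± 13.1, and the nitric oxide synthase gene NOS2 did not pass the low-count filter. RR replicate 4 held 75 CPM of ARG1 and 244 of CEACAM8, and without it the log2 fold changes went from 1.25 to -0.64 and from 0.55 to -1.56. For the sorting markers, CD33 was at 103 ± 52.7 CPM in leprosy and 44.3 ± 53.4 in HC and HLA-DRA at 2577 ± 1955 and 4352 ± 4329, so HLA-DRA transcripts were present in every group. Over the 3 HC libraries CD33 ran from 3.23 to 105 CPM, CD14 from 31.8 to 424 and HLA-DRA from 65.5 to 8722, and HC replicate 1 was the lowest in all 3 genes. That library also had the highest T cell score (7.45) and the lowest classical monocyte score (4.70) of the 12 libraries. Its low CD33 thus went against the enrichment and its low HLA-DRA went with it. The low CD33 bears on every comparison with HC. Marker transcripts departed from the enrichment in other libraries too. CD33 was at 17.6, 25.1 and 26.8 CPM in RR replicate 3, HC replicate 2 and ENL replicate 2. HLA-DRA was at 8722, 6665, 5068 and 4267 CPM in HC replicate 3, ENL replicate 3, RR replicate 4 and HC replicate 2. The HLA-DRA log2 fold change in leprosy was -0.76 and, without HC replicate 3, 0.24. ITGAM, which encodes CD11b, was at 552 ± 418 CPM against 136 ± 13.8. It was at 102, 54.8 and 23.9 CPM in ENL replicates 2 and 3 and RR replicate 3, below every HC library (127 to 152). In the remaining leprosy libraries it was at 391 to 1082 CPM.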

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

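In each group of 4 or 5 libraries, the highest and lowest library of each composition measure, list score and fixed gene was set against the others with Dixon's 95% limit. Of 110 such groups 10 had a library that stood apart, where chance gives about 1 in 20 groups, or 5.5 here. No explanation was tested for these values, and RR replicates 3 and 4 account for 6 of them.

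RR replicate 4 had 0.087% of its counts in hemoglobin genes, against 0.0013% in the next RR library, and 7.543% in mitochondrial ribosomal RNA genes, against 1.049%. Reads recovered from the normalized table came to 0.9346 times the raw total in RR replicate 4, with the nearest RR library at 1.0121, and to 1.4241 times in ENL replicate 1, with the nearest ENL library at 1.0139. ENL replicate 3 had the lowest ENL scores, in mean log2 CPM, for the cell cycle list (-0.544, next 0.522) and for T cell markers (2.148, next 3.68). RR replicate 3 had the lowest RR values for the stem and progenitor list (-1.119, next 0.011), for the sorting marker gene CD33 (17.635 CPM, next 115.24) and for ITGAM (23.925 CPM, next 391.32). RR replicate 5 had the highest IL10 of the RR libraries (1.5311 CPM, next 0.53916).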

How the results depend on the processing

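The alternatives chosen after the data were seen were the recovered reads, the surrogate variable, the library weights and both score covariates. No alternative called a gene between ENL and RR. The number of genes in ENL against HC (0), RR against HC (0) and leprosy against HC (44) moved with the test. DESeq2 called 1467, 450 and 1568, and voom with library weights 5253, 2205 and 5598. In the simulated data for those comparisons DESeq2 called 51, 86 and 73 unchanged genes and voom with weights 3, 3 and 8. Simulated genes varied independently and no library was noisier than its total makes it. These counts therefore do not measure how many of the real calls are false. With library totals, which put the median log2 fold change of all genes at -0.54 in ENL and -0.44 in leprosy (0.02 in each in the main test), 212 (6 higher, 206 lower) and 1047 (33 and 1014) were called. Without a filter 1 gene was called in RR. In leprosy against HC the stricter filter gave 84, limma-voom 104 (10 higher, 94 lower), the authors' normalized values 1 (higher, 0 shared with the 44), the surrogate variable 466 (85 and 381), an adjusted p under 0.10 339 (57 and 282), and the T cell score and the monocyte score 0 each. RLE, totals, DESeq2 and the weights called 38, 44, 44 and 44 of the 44. Leaving out 1 library gave 0 to 120 in ENL, 0 to 54 in RR and 0 to 318 in leprosy, each highest without HC replicate 3. Except for the lower threshold, the cause was not tested.

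Replicate numbers did not pair the libraries: the 10 same-number pairs had correlations of -0.30 to 0.387, and 2 of 11 libraries correlated best with their own number. With the number as a block 0 genes were called in leprosy against HC (44 without it) and in no other comparison a gene; list calls were 11, 21, 18 and 20 with the block, against 13, 19, 19 and 18 in ENL against RR, ENL, RR and leprosy against HC. Camera with an estimated correlation and fry's test of a move in 1 direction called 0 lists in each comparison; fry's test of change in either direction called 0, 5, 1 and 4 in the same order. Over 375 named genes and comparisons, 9845 of 10451 recomputed values kept their direction and side of the threshold, 421 passed it newly, 185 no longer passed and 0 called values reversed; 191 values in 67 uncalled results changed sign. In simulated data 0 to 2% of genes changed 2-fold passed by edgeR and 4 to 12% by DESeq2. With every library thinned to the smallest total, 0 to 21 genes were called in leprosy against HC (44 at full depth).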

Other observations

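The tests on the T cell and monocyte covariates, on the single ENL library and on handling were chosen after the results were seen. Of the gene groups not yet described, immature neutrophil granule genes had a median of -2.30 in ENL against RR with 0 of 20 positive, plasma cell markers -2.32 with 0 of 8, and platelet markers 1.38 with 14 of 14 (camera adjusted p = 0.00198, 0.00345 and 0.00197, and adjusted p = 0.735 with an estimated correlation). Without RR replicate 4 the granule median was 0.64 and the list was called higher, and without ENL replicate 3 it was not called (-1.92). The plasma call was lost without ENL replicate 3 (-1.93) or RR replicate 1 (-0.18), and the platelet call without ENL replicate 4 (0.67) or ENL replicate 1 (1.33). MHC class II genes (median -0.36) were lower by camera in ENL than in RR (adjusted p = 0.0239), and NK and cytotoxic markers (-0.55) likewise (adjusted p = 0.012); adjusted p = 0.735 with an estimated correlation for both. The class II call was lost without ENL replicates 1 (-0.46), 2 (0.00) or 4 (-0.46) or RR replicate 4 (-0.03), with -1.05 without ENL replicate 3 and -0.63 without RR replicate 3. The NK call was lost without ENL replicates 1 (-0.34), 2 (-0.31) or 3 (-0.17) or RR replicate 1 (0.47), with -2.24 without ENL replicate 4.

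Immediate-early genes were higher by camera in ENL than in RR (median 0.62, 24 of 25 positive, adjusted p = 0.0022), and mitochondrially encoded genes were lower (-0.22, 2 of 13 positive, adjusted p = 0.011); adjusted p = 0.735 with an estimated correlation for both. By edgeR 0 members of either list passed over all genes and 0 adjusted over the list alone. The immediate-early call was lost without ENL replicates 1 (0.22) or 4 (0.51) or RR replicates 3 (0.53) or 4 (0.50), with 1.21 without RR replicate 5. The mitochondrial call was lost without ENL replicates 1 (-0.23) or 2 (-0.01) or RR replicate 4 (-0.13), with -0.39 without ENL replicate 3, -0.40 without ENL replicate 4 and -0.15 without RR replicate 1.

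Type I interferon-stimulated genes, the antiviral response, were higher than in HC in ENL (median 0.85, 23 of 28 positive), in RR (0.71, 22 of 28) and in leprosy (0.91), with camera adjusted p of 0.00236, 0.000895 and 0.00119. With an estimated correlation the adjusted p = 0.574, 0.557 and 0.545, and the medians were 0.46 in ENL without ENL replicate 1 and 0.52 in leprosy without HC replicate 1. Glucocorticoid-responsive genes were higher as well, with medians of 1.35, 1.08 and 1.12 (camera adjusted p = 0.0116, 0.0123 and 0.0108, and adjusted p = 0.409, 0.384 and 0.415 with an estimated correlation). Vitamin D and antimicrobial genes had medians of 1.29, 1.06 and 0.99 (camera adjusted p = 0.00224, 0.000895 and 0.00126, and adjusted p = 0.409, 0.384 and 0.415 with an estimated correlation). Their ENL median was 0.85 without ENL replicate 2, the RR median 0.70 without RR replicate 4 and 0.57 without HC replicate 1, and the leprosy median 1.55 without HC replicate 3. No member of these lists passed by edgeR over all genes, and adjusted over the list alone 2 vitamin D genes passed in ENL and 2 in leprosy. Lists whose median and camera direction differ in sign numbered 2 in ENL against RR, 2 in RR against HC and 1 in leprosy against HC, none of them called.

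Genes called lower in leprosy than in HC included T lymphocyte genes, and RNA of T cells left in the HC libraries by the CD33 enrichment, which should remove them, is a candidate explanation: IL7R and TCF7, abundant T cell markers, were at 1012 ± 1010 and 211 ± 222 CPM in HC and 165 ± 267 and 22.1 ± 13.0 in leprosy. In HC replicate 3, however, TCF7 was at 17.2 CPM and the T cell score was 3.15, inside the leprosy range of 2.15 to 4.22. P2RY10 and LIMA1 were still at 60.8 and 24.4 CPM there, above every leprosy library (at most 17.9 and 8.27). LY9, also called lower, was not above them there (log2 CPM 2.54, leprosy up to 3.55). T cell RNA as scored does not account for P2RY10 and LIMA1 in that library. Within the 9 leprosy libraries the median correlation of the 43 genes with the T cell score was 0.382, above 100% of 10000 random gene sets of like expression (median 0.012), as predicted for T cell RNA. The random sets were drawn gene by gene, so genes that move together for another reason could exceed them too. No other cell score was compared, so the result does not single out T cell RNA. With the T cell score as a covariate the median log2 fold change went from -2.53 (interquartile range 1.51) to -1.44 (1.13) while the median SE went from 0.42 to 0.43, and 0 genes passed; the call ended because the fold shrank, and since the score differs between the groups, cell composition and diagnosis cannot be told apart for the remainder. Thinning every library to the smallest total left the median at -2.53 (SD 0.054 over 20 thinnings, before -2.53), with 0 to 21 genes called. Thinning keeps the expected ratios between libraries, so the median was bound to stay near its value and does not decide on depth. A change in the myeloid cells themselves stays open and was not tested.

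The higher cytokine list in ENL than in RR may reflect 1 ENL library. Without ENL replicate 2 the median went from 3.19 to -0.246, on the other side of 0. With 34 abundant genes removed before scaling the median of the 20 members left was 3.31. The 10 most abundant genes of a library held 8.30 to 13.6% of its counts in ENL and 7.00 to 14.0% in RR. With shares of this size the removal was bound to move the median little, so it adds no evidence of its own. The shares themselves argue against a distortion of the scaling as large as the median. Activation of the cells in that library before or after the blood was drawn stays open, and no test separated these.

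Immediate-early genes were higher in leprosy than in HC, which could come from the share of monocytes or from handling. With the classical monocyte score as a covariate the median went from 2.48 to 1.8 (camera adjusted p = 0.000114). The interquartile range of 2.24 is a spread between members, not the error of the median, and does not settle the part owed to monocytes. HC replicate 3, ENL replicate 3 and RR replicate 4 had monocyte scores of 9.34, 9.27 and 9.18. These lay near the 9.33 to 9.96 of ENL replicates 1 and 4 and RR replicates 1, 2 and 5. Their immediate-early scores were 4.72, 4.86 and 4.63, against 6.88 to 8.425. The monocyte score thus does not account for the low scores in those libraries. HC replicates 1 and 2 were low in both (monocyte scores 4.70 and 7.93). Of the 9 leprosy libraries 7 had a score above the highest HC library, ENL replicate 3 by little (4.86 against 4.72). Scores were 6.69 to 8.425 in ENL replicates 1, 2 and 4 and RR replicates 1, 2 and 5. They were 4.56 to 4.86 in ENL replicate 3 and RR replicates 3 and 4, beside 4.35 to 4.72 in HC, so the list varied widely within the diagnosis. No protocol text differs between the libraries, so handling could not be tested or told apart from diagnosis in the difference from HC.

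Other splits of the same libraries into groups of the same sizes were counted, the real one included. For genes at an unadjusted p under 0.05, the share of splits with as many was under the limit of 0.05 in 2 comparisons. These were ENL against HC (1 of 35, the lowest share possible, real 3321, highest other 3247) and leprosy against HC (2 of 100 drawn of 220, 3456 and 4936). Chance could not be excluded for RR against HC (3 of 56, 2190 and 3136) or ENL against RR (71 of 100 drawn of 126, 467 and 6092). At an adjusted p under 0.05 the real split of ENL against HC had 0 genes and 2 other splits had up to 3. The real unadjusted count of ENL against HC lay close to the highest other, and no correction was made for the 9 counts tested. The 2 low shares therefore do not exclude chance. For the 44 genes of leprosy against HC it could not be excluded either (6 of 100; highest other 1333). For the number of called lists it could not be excluded in ENL against RR (36 of 100; 13 and 19), ENL against HC (7 of 35; 19 and 23), RR against HC (12 of 56; 19 and 24) or leprosy against HC (11 of 100; 18 and 22). Splits with 6092 or 1333 genes, many times the real counts, point to a structure of the samples other than the labelled groups; the first 3 principal components held 26.5, 20.5 and 14.7% of the variance. Among the genes with the strongest loadings on the first, named after their values were seen, OLR1, a scavenger receptor gene, was at 296 to 766 CPM in ENL replicates 2 and 3 and RR replicates 3 and 4, at 0.161 to 7.20 in the other 5 leprosy libraries and at 0.38 to 74.1 in HC. GPNMB, a glycoprotein gene of macrophages, was at 347 to 1601, 1.08 to 4.03 and 19.3 to 636 CPM in the same libraries.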
